A study of Rattus norvegicus with 12 samples.

How the data were processed

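Total RNA from the striatum of both sides of the brain was measured on one-colour Agilent whole rat genome arrays, 1 male Sprague-Dawley rat per array and 12 arrays in all. Per the labels, the rats had breathed air, 1000 ppm carbon monoxide (CO), 3000 ppm CO or 5% oxygen (O2) for 40 minutes, and the brains were perfused with saline before dissection. Per the file headers, the arrays were extracted with Agilent Feature Extraction 10.7.3.1, and the processed signal of each spot is an intensity in arbitrary fluorescence units, with background subtracted and spatial trends removed within the array, and with no scaling between arrays. Mean spot signals and median local backgrounds are raw intensities per the file headers, and the other deposited columns used here are flags for spots well above background, outlying spots and saturated spots. The deposited series table holds log2 values, which followed the log2 processed signal of the same array with a correlation of at least 0.99996 across 41012 probes and were centred on each array's median. Probe positions in the headers are on the rat build rn4.

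The processed signal was taken to log2 and each array's 75th percentile was subtracted. Outlying spots were left out, repeated spots of a probe were averaged, and 14 probes with no usable spot on some array were dropped. Probe names were updated with a RefSeq gene table by accession, symbol or synonym, and 19705 of 41012 probes kept the name in the file. A gene was represented by its brightest probe over the 12 arrays, which mattered for 4494 genes with several probes. Of 35171 genes or unnamed transcripts, 29411 were well above background on at least 1 array and entered the comparison with air, and 27054 (13427 with a symbol) were well above background on at least 3 arrays and entered the model. Values of arrays not well above background were raised to that array's floor in comparisons with air, so such a difference is a bound.

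Each combination of exposure and time had 1 rat. A limma 3.58.1 model (R 4.3.3) with exposure and time as additive factors was fitted to all 12 arrays, which left 5 residual degrees of freedom and an estimated prior of 2.16, and its tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The residual also holds any interaction of exposure with time. The air array is the only one of its exposure, so it does not enter the comparisons of times, and for contrasts with air it was assumed to vary like the other arrays. Each exposed array was also set against the air array, counting genes at least 2-fold higher or lower, with no p-value because neither side has a replicate. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

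The comparisons, the rule for named genes, the alternatives and 22 gene lists were chosen before the data were examined. The lists were immediate early, hypoxia-inducible, oxidative stress and heme, heat shock, unfolded protein and integrated stress, glucocorticoid-responsive, inflammatory, apoptosis and p53, circadian clock, cAMP signalling and respiratory chain genes, and markers of medium spiny neurons, striatal interneurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelium and pericytes, blood cells, choroid plexus and ependyma, cortical neurons, and septal and thalamic neurons. In each array a list's median difference from air was ranked among 10000 random lists of the same size matched on expression level. In each model contrast, limma's camera (preset correlation 0.01, and again with an estimated correlation) and fry were run, adjusted over the lists of a contrast, and members were counted over all genes tested and adjusted over the list alone. The named genes were, per model contrast, the 10 largest rises and the 10 largest falls among genes with a symbol past the threshold, and per exposed array the 3 largest rises and the 3 largest falls with a symbol, with up to 4 members of any list in the outer 5% of its random lists; any list member may be named with its list.

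The alternatives were normexp background correction of the raw signals (offset 50), quantile normalization, the deposited series values, a stricter filter and no filter on dim probes, the mean over a gene's probes, a variance prior with trend and robust fitting, slide as a fixed factor or as a random block, position on the slide as a covariate, exposure without time, only 0, 2 and 6 h, the fit without the air array, leaving out each array in turn, fold changes of 1.5 and 3, the median of the 12 arrays as reference, and the estimated correlation of camera. Scan session as a fixed factor, the mean levels of 2 tissue marker lists as covariates, the fit without 1000 ppm CO at 6 h and 5% O2 at 0 h, and lists of mitotic genes and hypothalamic peptides were added after seeing the data. The model was tested on simulated data in which 200 of 27054 genes were changed: for 3000 ppm CO against 1000 ppm CO it found 50.5% of changes of 1 log2 unit, 81.5% of changes of 2 and 96.5% of changes of 4. For 3000 ppm CO against 5% O2 these shares were 34.5%, 77.5% and 93.5%, for 3000 ppm CO against air 0%, 51% and 91%, for 2 h against 0 h 32.5%, 75% and 97%, and for 12 h against 0 h 13%, 73% and 94.5%. The simulated noise was independent between arrays, with no effect of slide, session or tissue, so these shares do not cover such effects. No array was left out of the main comparisons, and 12 h after 5% O2 was not analysed here.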

Results

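The series follows gene expression in the rat striatum after 40 minutes of breathing CO, which binds hemoglobin and blocks oxygen transport, or a low-oxygen gas mixture. There was 1 rat right after air, 1 rat at each of 0, 2, 6 and 12 h after 1000 ppm CO and after 3000 ppm CO, and 1 rat at each of 0, 2 and 6 h after 5% O2. Each array measured 41012 gene probes, and between 72.9% and 78.7% of its spots were well above background with 0 saturated. The 75th percentile of the processed signal lay between 463.5 and 805.8 intensity units. Air and 3000 ppm CO at 0, 2 and 6 h shared slide 1, the 4 arrays of 1000 ppm CO filled slide 2, and 3000 ppm CO at 12 h shared slide 3 with the 5% O2 arrays. Slide 1 was scanned in an earlier session than slides 2 and 3. Differences between an exposed array and the air array have no replicate check, all 11 share that 1 array so that their agreement in direction is not independent, and the number of arrays limits the precision of every value.

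The first question was how expression moved on after the exposures ended. Right after all 3 exposures a small set of rapidly induced genes stood far above air, and by 2 h it had fallen back. Ccn1, which encodes a secreted matrix protein induced by growth factors and mechanical stress, was 4.18, 3.82 and 4.01 log2 units above air at 0 h after 1000 ppm CO, 3000 ppm CO and 5% O2. It was −4.02 ± 0.25 lower at 2 h than at 0 h (SE, 3 arrays against 3, adjusted p = 0.012), −4.21 ± 0.25 at 6 h (adjusted p = 0.00684) and −4.11 ± 0.29 at 12 h (2 arrays, adjusted p = 0.0219). Within 1000 ppm CO, 3000 ppm CO and 5% O2 taken singly, Ccn1 at 2 h differed from 0 h by −3.95, −4.37 and −3.74.

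The other genes that passed were also lower after 0 h. Klf2 and Klf4, Krüppel-like transcription factors known for their response to blood flow in endothelium, fell by 2.72 ± 0.19 (adjusted p = 0.015) and 2.22 ± 0.17 (adjusted p = 0.0211) at 2 h. At 6 h the same contrasts were −2.53 ± 0.19 for Klf2 and −2.53 ± 0.17 for Klf4, and Klf4 was at −2.44 ± 0.20 at 12 h (adjusted p = 0.0297). Apold1, an early response gene of vascular endothelium, fell by 4.05 ± 0.36 at 6 h (adjusted p = 0.0399) after standing 3.34, 4.09 and 4.96 above air at 0 h. Zfp36, whose protein marks inflammatory and growth-related mRNAs for decay, passed for lower at 2 h (adjusted p = 0.037) and 6 h (adjusted p = 0.0257), but only 1 of 3 arrays was well above background at each of these times, so the size of the fall was not measured. At 12 h it was not well above background on either array, at least 5.14-fold lower than at 0 h. On rn4 the probes lie on chromosome 2 from 243824388 to 243824447 for Ccn1 and chromosome 16 from 17942544 to 17942603 for Klf2. Those of the others lie on chromosome 5 from 73446994 to 73447053 for Klf4, chromosome 4 from 171907496 to 171907555 for Apold1 and chromosome 1 from 83486788 to 83486847 for Zfp36.

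**Figure D1:**
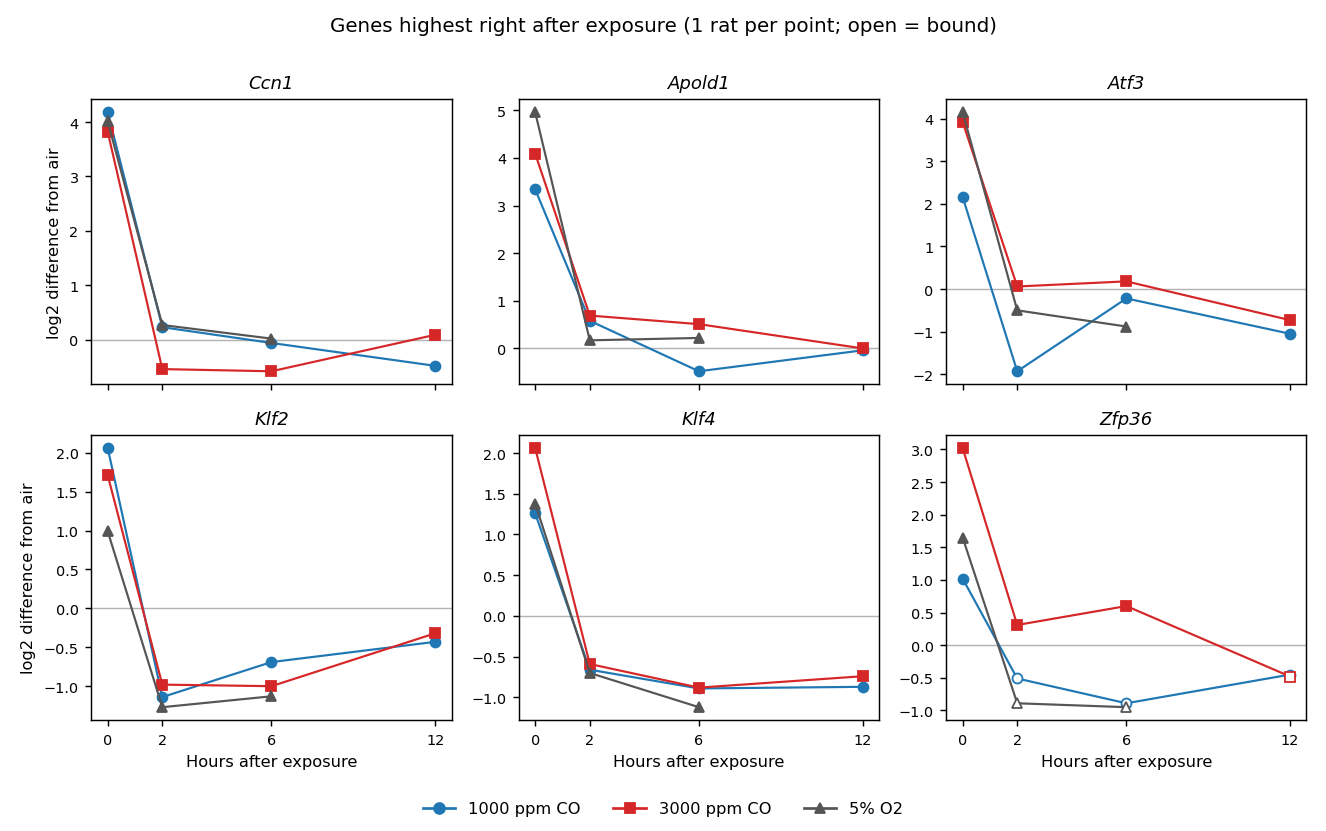
Log2 difference from the air array (vertical axis) against hours after exposure for 6 genes, 1 rat per point, with lines joining the rats of 1 exposure and open points for bounds where the probe was not well above background. All 6 genes were above air at 0 h after all 3 exposures, with Ccn1 at 4.18, 3.82 and 4.01, and lay near or below the air level from 2 h on.

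In all, 5 genes passed at 2 h, 6 at 6 h and 4 at 12 h, all lower than at 0 h, and 988, 743 and 1415 genes had an unadjusted p under 0.05. With slide as a random block 7, 7 and 2 genes passed, and with slide as a fixed factor 1, 2 and 2. Ccn1, 2 h against 0 h after exposure, was at −4.02 in both fits (adjusted p = 0.0013 and 0.00405). The 0 and 2 h arrays of each exposure shared a slide, so slide could not change this estimate. With position on the slide as a covariate 1, 0 and 1 passed, with normexp background correction 0, 0 and 0, and without 1000 ppm CO at 6 h and 5% O2 at 0 h, left out after seeing the data, 0, 0 and 0. At 2 h, 0 genes passed without 1000 ppm CO at 2 h, 3000 ppm CO at 0 or 2 h or any 1 of the 5% O2 arrays, while 1 passed without either 12 h array and 4 to 6 otherwise. At 6 h, 0 passed without any 1 of the 6 h arrays. The count was 2 without 1000 ppm CO at 2 h, 3000 ppm CO at 2 h or either 12 h array, 3 without 5% O2 at 0 h, and 4 to 8 otherwise. At 12 h, 0 passed without 1000 ppm CO at 2 or 12 h, 3000 ppm CO at 0, 2 or 6 h or any 1 of the 5% O2 arrays. The 12 h count was 2 without 3000 ppm CO at 12 h, 6 without 1000 ppm CO at 0 h and 8 without 1000 ppm CO at 6 h. When 1 array was left out Ccn1 at 2 h stayed between −4.15 and −3.81, and it was −3.74 with position on the slide as a covariate and −3.21 with normexp background correction.

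Immediate early genes, the transcription factors and signalling regulators that cells switch on within minutes of a stimulus, were lower at the later times, as a group with camera at all 3. Of 16 measured members, 8 at 2 h, 8 at 6 h and 9 at 12 h were lower when adjusted over the list alone, and 0 over all genes tested with limma. Atf3, a stress-induced transcription factor, was at −4.20 ± 0.49 at 2 h (0.000733 adjusted over the list alone, 0.161 over all genes), and it stood 2.16, 3.92 and 4.15 above air at 0 h after 1000 ppm CO, 3000 ppm CO and 5% O2. Btg2, an antiproliferative gene, was at −2.61 ± 0.35, Dusp1, a phosphatase that ends MAP kinase signalling, at −2.46 ± 0.35, and Fos at −1.79 ± 0.28. The camera test gave adjusted p = 1.43e-11 at 2 h, 1.05e-22 at 6 h and 1.62e-14 at 12 h, and adjusted p = 0.0484, 0.0101 and 0.0289 with an estimated correlation. The fry test of a common direction gave adjusted p = 0.0855 at 2 h, which does not pass, and 0.0095 and 0.0146 at 6 and 12 h. Over all lists and contrasts, camera passed 47 tests with the preset correlation, and these 3 were the ones that passed with an estimated correlation. Fry passed 3, immediate early genes at 6 and 12 h and hypoxia-inducible genes at 6 h.

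The list's median against air was 0.57, 0.44 and 0.26 at 0 h after 1000 ppm CO, 3000 ppm CO and 5% O2, at or above the 98.9th percentile of random lists. At every later time it was below air, from −0.27 to −1.28. The members split after 5% O2: Egr2, Egr4 and Arc, which follow synaptic activity in neurons, lay at −4.23, −2.94 and −2.65 at 0 h, while Btg2 and Dusp1 were 3.30 and 2.46 above air. In that array the median of the medium spiny neuron markers was −3.19. In the only other array with medium spiny neuron markers below air, 1000 ppm CO at 6 h (median −0.84), Egr2, Egr4 and Arc were at −3.37, −2.30 and −2.43. Egr2 was also at −2.67, −2.65 and −2.34 in 1000 ppm CO at 12 h and 5% O2 at 2 and 6 h. There the marker medians were above air, at 0.43, 0.07 and 0.44. At 0 h after 1000 and 3000 ppm CO, with marker medians of 1.04 and 0.16, Egr2 was at −0.49 and 0.18.

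Genes induced by glucocorticoids, the hormones of the stress response, stood above air in 9 of the 11 exposed arrays, with medians from 0.26 to 0.99 at or above the 99.7th percentile of random lists. The exceptions were 1000 ppm CO and 5% O2 at 6 h, with medians of −0.01 and −0.02. Zbtb16, a zinc finger transcription factor, was highest at 2 h after all 3 exposures, at 1.90, 2.84 and 2.68 above air. After 1000 ppm CO Zbtb16 was at −0.32 at 6 h and again high at 12 h, at 1.72. It was the 1 list member that passed at 2 h against 0 h, higher by 2.36 ± 0.49 (0.0247 adjusted over the list alone, 0.901 over all genes), and the differences within 1000 ppm CO, 3000 ppm CO and 5% O2 were 2.22, 2.55 and 2.32. Fkbp5, a cochaperone that limits the glucocorticoid receptor, was at 0.74, 1.25 and 1.13 against air at 2 h, and Sgk1, a kinase that regulates ion channels, at 1.59, 0.81 and 1.07 at 0 h. Fkbp5 was below air in 1000 ppm CO at 6 h (−0.61) and 5% O2 at 0 h (−1.26). Cdkn1a of this list was above air just in 5% O2 at 0 and 2 h (0.48 and 0.95). After 5% O2 at 2 h, 7 of 14 members were at least 2-fold above air, among them Pdk4 at 1.58 and Tsc22d3 at 1.18. At 6 h Arrdc2 and Errfi1 were lower than at 0 h (−0.83 ± 0.19 and −0.73 ± 0.15) and Sult1a1 higher (0.91 ± 0.24) adjusted over the list alone. Sult1a1 was also higher at 12 h (1.23 ± 0.28). The list test at 2 h gave adjusted p = 0.0225 for higher, and adjusted p = 0.649 with an estimated correlation; at 6 h it gave 0.0232 for lower and adjusted p = 0.589 with an estimated correlation.

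Among hypoxia-inducible genes, Slc2a1, the glucose transporter of the blood-brain barrier, was above air in all 11 exposed arrays, from 0.26 to 1.46. Under the additive model it was 0.88 ± 0.16 above air after 1000 ppm CO and 0.89 ± 0.16 after 5% O2 (0.0167 and 0.0159 adjusted over the list alone, 0.0966 and 0.324 over all genes). It was 0.51 ± 0.11 higher at 2 h than at 0 h (0.0349 adjusted over the list alone). Adm, a vasodilator peptide, was 2.82 above air right after 5% O2 and between 0.05 and 1.01 elsewhere. Ddit4, an inhibitor of mTOR signalling, was 0.93, 1.13 and 0.73 above air at 0 h and lower at 6 h than at 0 h by −1.25 ± 0.19 (0.00532 adjusted over the list alone, 0.569 over all genes). The median of the 18 genes was 0.31 in 1000 ppm CO at 2 h (99.6th percentile of random lists). It was 0.10, 0.20 and 0.23 in 3000 ppm CO at 0, 2 and 12 h (99.2nd, 99.4th and 97.9th). After 5% O2 it was 0.17, 0.01 and −0.03 at 0, 2 and 6 h (95.6th, 62.7th and 30.7th). In 1000 ppm CO at 0, 6 and 12 h and 3000 ppm CO at 6 h it lay between 0 and 0.15, at or below the 91.3rd percentile. The list passed at 6 h for lower (camera adjusted p = 0.0171) and had adjusted p = 0.309 with an estimated correlation and 0.0199 with fry.

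**Figure D2:**
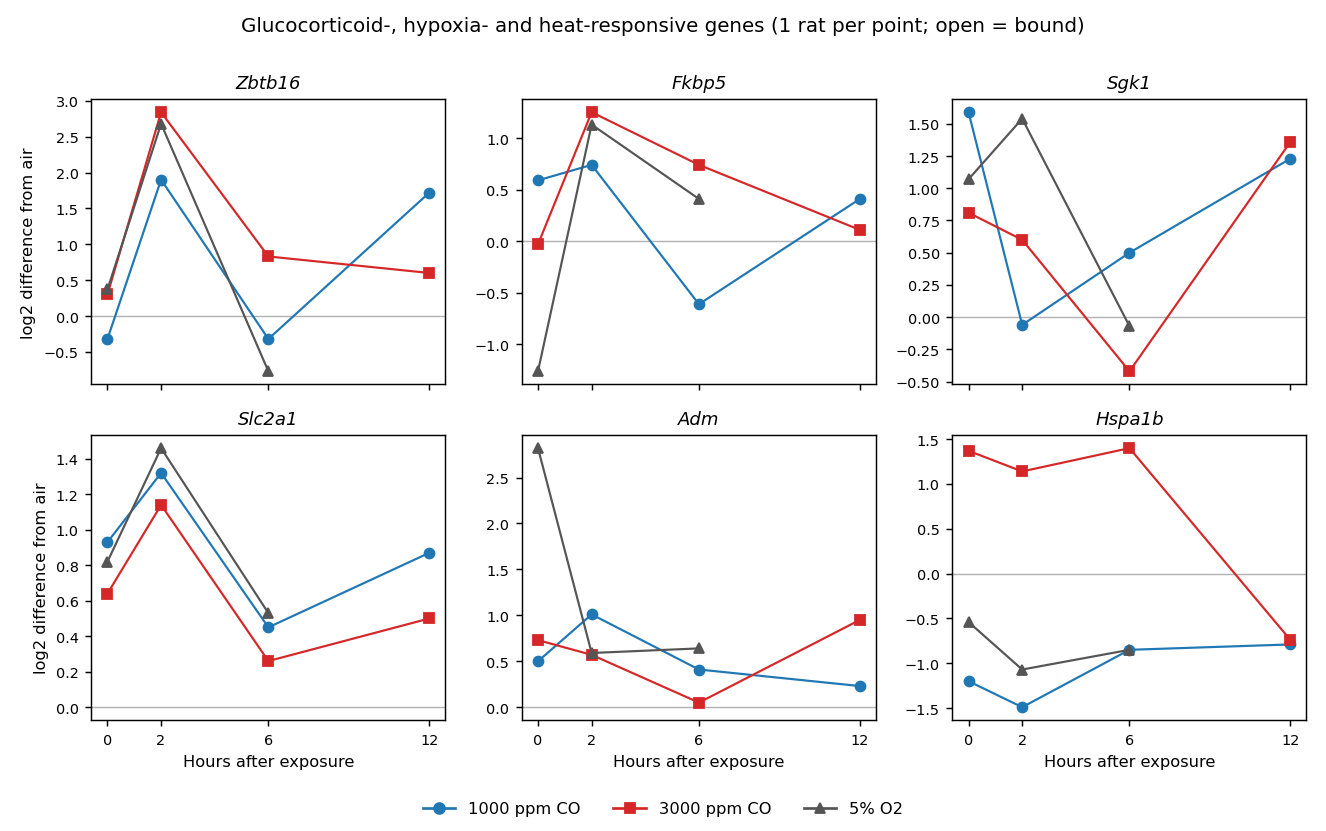
Log2 difference from the air array against hours after exposure for 3 glucocorticoid-responsive genes (Zbtb16, Fkbp5, Sgk1), 2 hypoxia-inducible genes (Slc2a1, Adm) and the heat shock gene Hspa1b, 1 rat per point. Zbtb16 was highest at 2 h after all 3 exposures, and Hspa1b was above air only in 3000 ppm CO at 0, 2 and 6 h, the 3 arrays on the slide of the air array.

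Heat shock genes, which encode chaperones, were below air as a list in all 11 arrays, with medians from −0.09 to −0.48; in all but 3000 ppm CO at 0 h the median was at or under the 1.8th percentile. A high level in the air array alone would put all 11 below it. Hspb1, a small heat shock protein gene, ranged from −0.34 to −1.26. Hspa1b went the other way in 3000 ppm CO at 0, 2 and 6 h, at 1.37, 1.14 and 1.40, and was between −0.54 and −1.49 elsewhere, 3000 ppm CO at 12 h included. The list was lower against air with camera after 1000 ppm CO (adjusted p = 0.0494) and after 5% O2 (adjusted p = 0.0478). It had adjusted p = 0.85 and adjusted p = 0.888 with an estimated correlation. Unfolded protein and integrated stress genes were at or under the 1.5th percentile in 1000 ppm CO at 0 and 2 h (−0.45 and −0.33) and 3000 ppm CO at 2 and 6 h (−0.28 and −0.45). Trib3, a pseudokinase of the integrated stress response, was 1.72 above air in 5% O2 at 0 h. Their list test passed for lower at 2 h (adjusted p = 0.0209) and in 3000 ppm CO against 5% O2 (adjusted p = 0.0268), with adjusted p = 0.649 and adjusted p = 0.695 with an estimated correlation.

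Hmox1, which breaks heme down and releases CO, lay between −0.02 and 0.56 against air in the 11 arrays. The oxidative stress and heme list stood at the 99th percentile in 3000 ppm CO at 2 h (0.25) and the 97.9th in 5% O2 at 0 h (0.24), and no member passed a model contrast. The metallothionein Mt2A was at 1.22 in the first of these and 0.45 in the second. Inflammatory genes were above air in 3000 ppm CO at 6 h (0.37, 98.1st percentile) and below it in 1000 ppm CO at 0 and 12 h (−0.37 and −0.38). The chemokine Ccl3 was above air in all 11 arrays, highest at 2.19 and 2.48 in 3000 ppm CO at 2 and 6 h, and Ccl2 was at 2.91 in 5% O2 at 0 h. The inflammatory list was lower at 12 h than at 0 h (adjusted p = 0.00498, and adjusted p = 0.672 with an estimated correlation). Circadian clock genes were at or above the 98th percentile in 8 arrays, with medians from 0.16 to 0.52. Dbp and Nr1d1, both targets of the core clock, were above air in all 11. At 12 h Per2, Dbp and Bhlhe41 were higher than at 0 h by 0.72 ± 0.12, 0.82 ± 0.24 and 0.49 ± 0.12 adjusted over the list alone. The list had adjusted p = 0.028, and adjusted p = 0.672 with an estimated correlation. The labels give no time of day.

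Some tissue markers differed between arrays by more than any of these groups, namely those of choroid plexus and ependyma, of septal and thalamic neurons and of medium spiny neurons. Choroid plexus and ependyma markers were below air in all 11 arrays. Ttr, the thyroxine carrier secreted by choroid plexus, was at −7.41, −5.83, −0.58 and −1.03 at 0, 2, 6 and 12 h after 1000 ppm CO, and at −1.39, −0.31 and −0.26 at 0, 2 and 6 h after 5% O2. After 3000 ppm CO it lay between −3.56 and −6.35. The list's medians were −6.03, −5.17, −0.72 and −1.76 after 1000 ppm CO, −3.70, −4.79, −4.52 and −5.46 after 3000 ppm CO, and −2.23, −0.71 and −0.36 after 5% O2. Sostdc1 of this list was −8.17 in 1000 ppm CO at 0 h. There and in other arrays Kcnj13 (−8.69) and Cnmd (at least 478-fold lower) were also among the largest falls, while the largest falls were other genes in 1000 ppm CO at 6 and 12 h and 5% O2 at 0 and 2 h, such as Gpr6 at −4.65 in 5% O2 at 0 h. Against air in the model the list was lower with camera after 3000 ppm CO, 1000 ppm CO and 5% O2 (adjusted p = 7.32e-15, 2.97e-05 and 0.0266), and had adjusted p = 0.5, 0.85 and 0.917 with an estimated correlation; 7 of 11 members after 3000 ppm CO and 0 after the others were lower adjusted over the list alone. It also passed camera for lower in 1000 ppm CO against 5% O2 (0.0011) and for higher at 6 and 12 h (3.73e-07 and 0.0212), with adjusted p = 0.84, 0.489 and 0.672 with an estimated correlation.

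Medium spiny neurons, the main striatal cell type, showed their lowest markers in 5% O2 at 0 h. There 12 of 14 markers were at least 2-fold below air, with the dopamine receptors Drd1 at −3.98 and Drd2 at −3.19 and the adenosine receptor Adora2a at −3.63. The list's median was −0.84 in 1000 ppm CO at 6 h and between 0.07 and 1.04 in the other 9 arrays. Septal and thalamic neuron markers were at 1.52 and 1.18 in those same low arrays, with Slc17a6, a vesicular glutamate transporter of subcortical neurons, at 2.02 and 1.38. They were at −2.50 and −2.72 in 1000 ppm CO at 0 and 2 h and at −2.27 and −2.36 in 3000 ppm CO at 2 and 6 h. In 3000 ppm CO at 12 h the septal and thalamic list was at 0.82, while medium spiny neuron markers were above air too, at 0.31. Pmch, a neuropeptide gene of the lateral hypothalamus, was 6.39 above air in 1000 ppm CO at 6 h and 5.98 in 5% O2 at 0 h, and Avp, the vasopressin gene, 3.76 and 2.47. Pmch was also above air, from 2.11 to 3.44, in 1000 ppm CO at 12 h, 3000 ppm CO at 0 and 12 h and 5% O2 at 2 and 6 h, and Avp was at 2.80 in 1000 ppm CO at 12 h. Cortical neuron markers were highest in 3000 ppm CO at 2 and 6 h (1.25 and 0.70) and lowest in 5% O2 at 6 h (−1.02). Striatal interneuron markers ranged from −0.88 in 5% O2 at 0 h to 0.57 in 1000 ppm CO at 0 h.

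Blood cell markers stood out in 3000 ppm CO at 6 h, with a median of 1.48 and the globins Hbb, Hba-a3 and Hbb-b1 at 5.30, 4.88 and 4.65. Alas2, the enzyme of heme synthesis in red cell precursors, was at 3.60. The neutrophil genes S100a8 and S100a9 were above air in all 11 arrays, highest in 3000 ppm CO at 2 h (3.36 and 3.02). Oligodendrocyte markers had medians from 0.41 to 0.56 in 1000 ppm CO at 12 h, 3000 ppm CO at 0 and 12 h, and 5% O2 at 0 and 2 h, and −0.40 and −0.28 in 3000 ppm CO at 2 and 6 h. Microglia markers ranged from −0.26 to 0.38, endothelial and pericyte markers from −0.37 to 0.54, astrocyte markers from −0.03 to 0.26 and oligodendrocyte precursor markers from −0.23 to 0.55. P2ry12, a purinergic receptor of resting microglia, was above air in all 11 arrays, from 0.62 to 1.27. Apoptosis and p53 genes lay between −0.12 and 0.13, cAMP signalling genes between −0.23 and 0.18 and respiratory chain genes between −0.14 and 0.23. At 2 h the phosphodiesterase Pde4d of the cAMP list was lower than at 0 h (−0.62 ± 0.13, 0.0379 adjusted over the list alone).

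**Figure D3:**
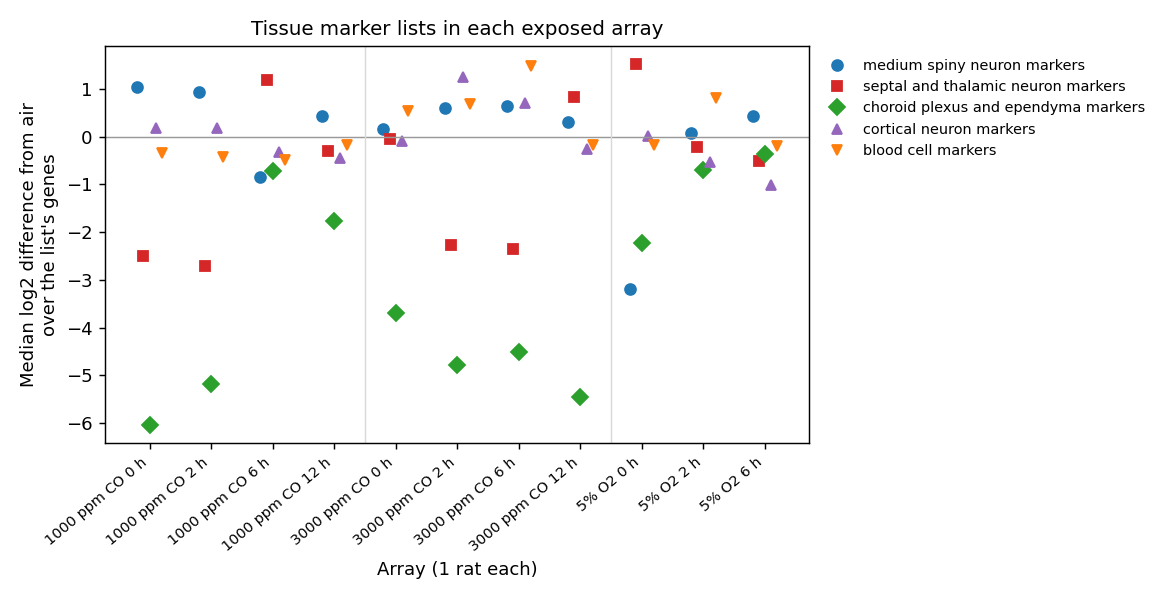
Median log2 difference from the air array over the genes of 5 tissue marker lists (vertical axis), for each exposed array (1 rat each, horizontal axis), with vertical lines between exposures. Choroid plexus and ependyma markers lay between −0.36 and −6.03 in all 11 arrays, and medium spiny neuron markers reached −3.19 in 5% O2 at 0 h, where septal and thalamic neuron markers were at 1.52.

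Against the air array alone, 1000 ppm CO had 2693, 3071, 2604 and 2241 genes at least 2-fold different at 0, 2, 6 and 12 h, and 5% O2 had 2581, 1187 and 1162 at 0, 2 and 6 h. After 3000 ppm CO the counts were 1132, 1677 and 1964 at 0, 2 and 6 h on the slide of the air array and 2279 at 12 h on another slide. For scale, any 2 of the 12 arrays differed in a median of 1325.5 genes (614 to 3217) on the same slide and 1902.5 (912 to 5322) on different slides. Most pairs on the same slide also shared an exposure and few on different slides did, so this gap does not measure slide alone. The pairs with the air array are among them. Over each exposed array against the air array, the medians were 909 genes higher and 1332 lower, and 1165 higher and 1096 lower with the deposited series values. Clcf1, a cytokine of the interleukin-6 family, was among the largest rises after 1000 ppm CO at 2 and 12 h (3.28 and 3.55) and after 5% O2 at 6 h (2.71), and was at −0.93 in 5% O2 at 0 h. Robo3, an axon guidance receptor, was at 3.61 and 4.39 in 3000 ppm CO at 2 and 6 h and between −0.50 and 1.29 elsewhere.

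The model set the air array, taken at 0 h, against each exposure with the differences between times removed, so its values refer to 0 h. On that footing Ccn1 was 4.05 ± 0.38 higher after 1000 ppm CO (adjusted p = 0.0451), while the 4 arrays themselves were at 4.18 at 0 h and between −0.48 and 0.23 later. Mat1a, which makes the methyl donor S-adenosylmethionine, was −3.38 ± 0.34, and Hrh4, a histamine receptor, −1.49 ± 0.17, both with adjusted p = 0.0451; Mat1a was also below air on the other 7 exposed arrays, from −2.01 to −3.17. Zmynd15 and Cox6c-ps1 were −2.30 ± 0.26 (3 of 4 arrays well above background) and −1.99 ± 0.24. Nfatc2ip and Pdia6l1 were at least 4.35-fold and 10.9-fold lower, and the olfactory receptor Or5b104b at least 2.09-fold. With normexp background correction Or5b104b turned to 0.27 and Nfatc2ip was at −0.06. Cgnl1 was −3.87 ± 0.45, well above background on 1 of 4 arrays. On the other 7 exposed arrays Nfatc2ip lay from −1.75 to −2.46 and Zmynd15 from −1.01 to −1.84, bounds included. Pdia6l1 lay there from −0.45 to −1.74 and Cgnl1 from −0.59 to −2.37. A high level in the air array alone would give such falls. In total 41 genes passed after 1000 ppm CO (11 higher, 30 lower; 11 and 13 with the deposited series values), 2 after 3000 ppm CO and 1 after 5% O2, while 3357, 1255 and 2054 had an unadjusted p under 0.05. The named gene after 3000 ppm CO was Calml3, a calmodulin-like gene of epithelium, at least 2.9-fold lower and not well above background on any 3000 ppm CO array. Against air, Calml3 lay between −1.27 and −1.86 on all 11 exposed arrays, most of these values being bounds. Immediate early genes gave 0 over all genes and 4 higher adjusted over the list alone after each exposure, Atf3, Btg2, Dusp1 and Ier2. Btg2 was at 2.40 ± 0.52 after 1000 ppm CO, 2.92 ± 0.52 after 3000 ppm CO and 2.93 ± 0.53 after 5% O2 in these values for 0 h, and between −0.18 and 0.22 against air in the 8 later arrays.

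All 4 arrays of 1000 ppm CO were on another slide than air, and the count was 0 with slide as a random block or scan session as a fixed factor. Without 1000 ppm CO at 12 h or 3000 ppm CO at 12 h the count was 234, without 1000 ppm CO at 6 h it was 1, and without any other single exposed array 0. The counts for 3000 ppm CO against air were 3 without 1000 ppm CO at 0 or 6 h, 2 without 5% O2 at 6 h and 0 without any other exposed array, and 0 with slide as a fixed factor (Calml3 at −3.80, adjusted p = 0.0672). For 5% O2 against air the count was 1 without 1000 ppm CO at 6 or 12 h or 3000 ppm CO at 12 h, and 0 without any other exposed array or with slide as a fixed factor.

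The comparison of 3000 ppm with 1000 ppm CO sets the higher dose against the lower at matched times. Hspa1b, an inducible chaperone of the heat shock response, was 1.88 ± 0.41 higher after 3000 ppm (4 arrays against 4, adjusted p = 0.0483), and Car9, a hypoxia-inducible carbonic anhydrase, 0.66 ± 0.11 higher (adjusted p = 0.0189). At 12 h, on other slides, Hspa1b was at −0.74 against air after 3000 ppm and −0.79 after 1000 ppm. Car9 was near air after 3000 ppm (−0.02 to 0.17) and 5% O2 (−0.03 to 0.06), and low in the 4 arrays of 1000 ppm on slide 2 (−0.43 to −0.74). These were the members of the 22 lists that passed over all genes. Among genes measured well above background on all 8 arrays, the largest falls with a symbol were in RT1-N2, a class I histocompatibility gene (−1.29 ± 0.23, adjusted p = 0.0258), C10h5orf15 (−1.29 ± 0.22, adjusted p = 0.0221), the hair keratin Krt73 (−1.37 ± 0.25) and the sperm mitochondrial gene Smcp (−1.29 ± 0.23). On slide 1 the 3000 ppm arrays differed from air by −0.89, −0.18, 1.21 and 1.69 in these genes, in that order. On slide 3, 3000 ppm CO at 12 h differed from the 5% O2 mean by −1.37, 1.01, 0.43 and 0.15. No value was raised to the floor here, and Krt73 and Smcp were not well above background on the air array. With the air array raised to its floor, the slide 1 differences at 0, 2 and 6 h were 0.94, 0.4 and 0.7 for Krt73. For Smcp they were 1.09, 0.59 and 0.96.

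The 10 largest rises with a symbol were dim genes, well above background on none of the 1000 ppm arrays: the olfactory receptors Or4c103b and Or9k2b, the vomeronasal receptors Vom2r45 and Vom2r79, and Muc20, Hnf4g, Pdia6l1, Pabpc2, Adrb3 and Ccnjl. Or4c103b, Muc20 and Pdia6l1, above background on all 4 arrays of 3000 ppm, were at least 3.22-fold, 2.64-fold and 5.53-fold higher. Normexp background correction turned the direction of 9 of the 10, Or4c103b (−0.11) and Muc20 (−0.20) included, and left Pdia6l1 at 0.23. The other 6 named falls were also dim on most or all 3000 ppm arrays: Or1e27b, Olr673, Cetn1, Calml3, Or5h18 (at least 2.27-fold lower) and Slfn4. Of 310 tested olfactory, vomeronasal and trace amine receptors, a class counted after seeing the data, 123 passed. In this contrast 1435 genes passed, 1296 higher and 139 lower, 576 of them with a symbol, and the split was 1042 higher and 260 lower with quantile normalization. No tissue marker passed over all genes, with list medians of −1.06 for choroid plexus and ependyma, −0.08 for medium spiny neurons and 0.16 for septal and thalamic neurons.

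**Figure D4:**
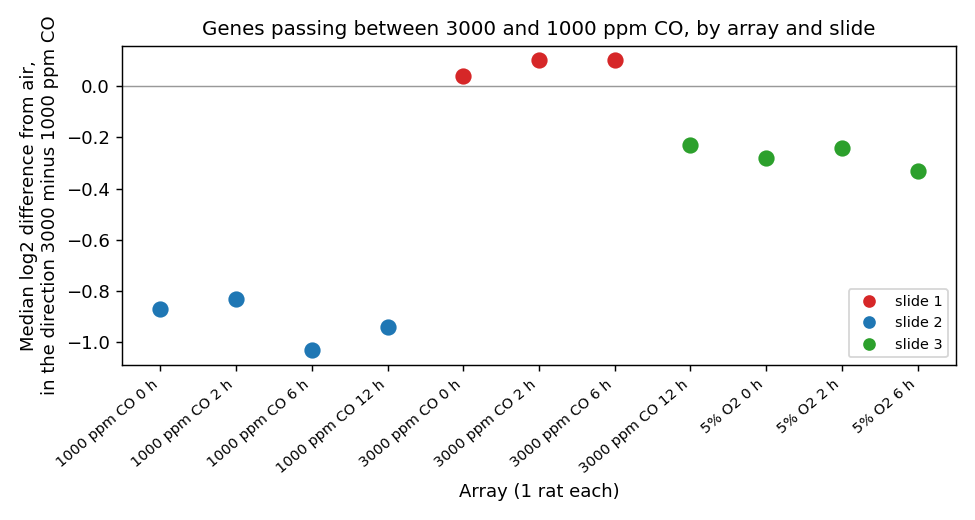
Median log2 difference from the air array over the genes that passed between 3000 and 1000 ppm CO, signed in the direction of 3000 minus 1000 ppm, for each exposed array (1 rat each), coloured by slide. Values not well above background were used as measured, without raising them to the floor. The 3 arrays of 3000 ppm CO on slide 1 lay between 0.04 and 0.10, the 4 arrays on slide 2 between −0.83 and −1.03, and the 4 on slide 3 between −0.23 and −0.33, the 12 h array of 3000 ppm CO among them.

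No slide held both sides of 3000 ppm CO against 1000 ppm CO, so slide and dose cannot be told apart. Only 1 array of 3000 ppm CO lay off slide 1, that of 12 h, on slide 3. It had a median of −0.23 in the direction of the contrast against −0.28, −0.24 and −0.33 in the 5% O2 arrays beside it. With slide as a random block 0 genes passed, with scan session as a fixed factor 1, and with normexp background correction 21. That correction moved the median difference of all genes by −0.227. Leaving out 1 array gave 2298 genes without 1000 ppm CO or 3000 ppm CO at 12 h, and 200, 239 and 436 without 3000 ppm CO at 2, 0 and 6 h. It gave 604 and 365 without 1000 ppm CO at 0 and 2 h, and 865, 631 and 870 without 5% O2 at 0, 2 and 6 h.

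For 3000 ppm CO against 5% O2, which sets CO beside plain lack of oxygen, 0 genes passed with limma, and 3885 had an unadjusted p under 0.05. The lists that differed included tissue markers: 7 of 11 choroid plexus and ependyma markers were lower after 3000 ppm CO adjusted over the list alone, such as Kcne2 at −4.57 ± 1.22 and Kl at −4.63 ± 1.25 (4 arrays against 3). The list had camera adjusted p = 2.39e-06, adjusted p = 0.695 with an estimated correlation and 0.362 with fry. Immediate early genes were higher with camera (adjusted p = 0.0108), with adjusted p = 0.695 with an estimated correlation and 0.281 with fry. Oligodendrocyte markers had 4 of 10 lower adjusted over the list alone, Cnp, Mag, Mog (−0.82 ± 0.21) and Opalin, with camera adjusted p = 1.76e-05, and adjusted p = 0.695 with an estimated correlation. Hspa1b was 1.82 ± 0.46 higher and Cryab −0.75 ± 0.20 adjusted over the list alone, with Hspa1b at 1.37, 1.14 and 1.40 against air on slide 1 and at −0.74 on slide 3 beside the 5% O2 arrays. Slide as a fixed factor also gave 0 genes, and leaving out either 12 h array or adding slide position gave 108.

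Between 1000 ppm CO and 5% O2, 3 named genes were higher after CO: Ska1 (1.77 ± 0.25, adjusted p = 0.0439, well above background on 2 of the 3 arrays of 5% O2) and Pbk (0.80 ± 0.12, adjusted p = 0.0464), both of dividing cells, and the kinase gene Hunk (0.96 ± 0.13, adjusted p = 0.0439). Lower after CO were Cox6c-ps1, named as a cytochrome oxidase pseudogene (−1.57 ± 0.16, adjusted p = 0.025), the receptor gene Gpr31 (−1.33 ± 0.17) and the olfactory receptor Or6c69b (−1.43 ± 0.20), all above background on all 7 arrays. The other 7 named falls were in genes well above background on none of the 1000 ppm arrays, Muc20, Pdia6l1 (at least 3.61-fold lower), Or4c103b, Olr385, Nutm2f, Or6d14 and Or4k42b. With normexp background correction all 7 turned to higher, Pdia6l1 at 0.15 among them, and so did Gpr31 (0.08), while Cox6c-ps1 and Or6c69b kept their direction. In total 147 genes passed, 5 higher and 142 lower, with 3437 at an unadjusted p under 0.05. Medium spiny neuron markers had a list median of 1.36, camera adjusted p = 0.000579 and adjusted p = 0.84 with an estimated correlation. Car9 and Per1 passed adjusted over the list alone (−0.59 ± 0.12 and 0.57 ± 0.13).

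For 1000 ppm CO against 5% O2 no slide held arrays of both exposures, so slide and exposure cannot be told apart here either. Slide as a random block gave 0 genes, as did normexp background correction, which moved the median difference of all genes by 0.254. The count was 1783 without 1000 ppm CO at 6 h and 5 without that array and 5% O2 at 0 h, a setting chosen after seeing the data. It was 153 without either 12 h array and 0 without any other single exposed array.

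Set against the mean of the other exposures, 3000 ppm CO was higher in Tsg101, a gene of endosomal sorting (1.92 ± 0.23, 4 arrays against 7, adjusted p = 0.0286), and in Ghrl, the ghrelin gene (1.75 ± 0.25, adjusted p = 0.036). It was lower in RT1-N2 (−1.46 ± 0.21, adjusted p = 0.036), the desmosomal cadherin Dsg2 (−1.41 ± 0.20, adjusted p = 0.036), Spindoc (−1.0 ± 0.15), the cell cycle regulator Rb1 (−0.63 ± 0.11, adjusted p = 0.0457) and the neuronal gene Aplp1 (−0.54 ± 0.10). On slide 1, the 3 arrays of 3000 ppm CO differed from air by 0.01 in Tsg101, 0.20 in Ghrl, 0.04 in Rb1 and −0.03 in Aplp1, and by −0.89 in RT1-N2 and −1.73 in Dsg2. On slide 3, 3000 ppm CO at 12 h differed from the 5% O2 mean by 0.26, 0.12, 0.07 and 0.29 in the first 4 of these and by −1.37 in RT1-N2 and −1.22 in Dsg2. Among the other genes, Vom2r45, Or4c103b, Pdx1, Ccnjl, Pabpc2, Knstrn, Prss46, Pdia6l1, Calml3, Cetn1, Olr673 and Or5h18 were not well above background on all arrays, and Vom2r45, Pdx1, Pabpc2 and Prss46 turned direction with normexp background correction (−0.06, −0.08, −0.04 and −0.05).

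In all, 395 genes passed for 3000 ppm CO against the mean of 1000 ppm CO and 5% O2, 359 higher and 36 lower, with 5480 at an unadjusted p under 0.05. Oligodendrocyte markers Cnp, Mag and Mog were lower adjusted over the list alone (Mag −0.69 ± 0.14), with camera adjusted p = 0.000497, and adjusted p = 0.908 with an estimated correlation. Scan session as a fixed factor left 1 gene, slide as a random block 0, and the fit without 1000 ppm CO at 6 h and 5% O2 at 0 h, chosen after seeing the data, 0. Leaving out 1 array gave 1618 without either 12 h array, 581 without 1000 ppm CO at 6 h, 22 without 1000 ppm CO at 0 h and 0 without any other exposed array.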

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

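The tests of technical causes in this part were chosen only after the results were seen, apart from the regroupings of the arrays, which were planned.

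The 1 result that stood apart was the mean level of the unfolded protein and integrated stress genes in 1000 ppm CO at 6 h, at 0.77 against 0.35 to 0.41 in the other 3 arrays of that exposure, with a gap of 0.85 of the range. It was 1 of 48 sets of 4 arrays looked at, and chance sets about 1 in 20 apart in this way. In the same array medium spiny neuron markers were at −0.84 against air and septal and thalamic neuron markers at 1.18, opposite in sign to the other 3 arrays.

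The genes that passed between 3000 and 1000 ppm CO were mostly dim and parted by slide. Of 35 splits of these 8 arrays, the real one gave 1435 genes and the highest other gave 1. The real split also parts slide 2 from the other slides, and every other split divides slide 2. The splits therefore cannot exclude chance for dose. With slide as a random block 0 genes passed, and with scan session as a fixed factor 1. A slide or scan session effect stays open: among the 3000 ppm CO and 5% O2 arrays, the split by slide gave 352 genes, the highest of 35 splits, against 0 by exposure, a value already seen when the test was chosen. Signal close to background stays open, since with normexp background correction the genes' median difference went from 0.93 (quartiles 0.71 and 1.27) to 0.1 (quartiles −0.26 and 0.61), and 72.8% of the genes lay under the median level. Dose stays open too: 950 genes differing at least 2-fold at 0 and 2 h differed by a median of 1.31 at 6 h, where the sessions differ, and 0.54 at 12 h, where they match, but 5% O2 also differed from 1000 ppm CO by 0.63 at 6 h, so dose and slide cannot be told apart.

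Tissue marker lists differed strongly between arrays, within each exposure too. A lower share of medium spiny neurons in 5% O2 at 0 h with nothing added stays open. The medians of the 3 other neuron lists spanned 2.4 log2 units in this 1 array, instead of rising alike. They were 1.52 (septal and thalamic), 0.02 (cortical) and −0.88 (interneuron). The quartiles of the first and last lay apart (0.88 to 1.87 and −1.03 to 0.11), while those of the cortical list (−0.4 to 0.89) overlapped both. The test took interneurons as unchanged, so it cannot decide on a fall of interneurons along with medium spiny neurons. Tissue outside the striatum in some samples may account for the pattern: over the 12 arrays, the septal and thalamic list fell as the medium spiny neuron list rose (Pearson r = −0.76, permutation p = 1e-05, the smallest that 100000 permutations can give; Spearman rho = −0.94, permutation p = 3e-05). The adjusted p over these 2 correlations were 2e-05 and 3e-05, and r was −0.84 without the 2 farthest arrays. No dissection record was available to test this further. The list tests by exposure given above cannot tell a change made by the exposures from a difference in dissection.

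The genes lower at 2, 6 or 12 h than at 0 h made 15 calls in 6 genes. Tissue makeup, as far as 2 tissue marker lists measure it, stays open. With both lists as covariates the calls kept a median share of 1.01 of their log2 fold (0.9 to 1.08). However, 0 of the 15 still passed, and the rule for arguing against tissue makeup also asked that most of them pass. Tissue that these 2 lists do not mark stays open as well. Ccn1 at 2 h went from −4.02 ± 0.25 to −3.74 ± 0.27, and the call ended with 3 residual degrees of freedom in place of 5. Slide position stays open too. Within each exposure the arrays of 0, 2 and 6 h lay in order of position, so only the 12 h arrays tell position from time. The covariate fit can therefore hardly decide on position. In it the median share was 1.02 (0.87 to 1.12) and 2 of the 15 passed, Ccn1 at 2 h among them at −3.74, with 4 residual degrees of freedom. Time since exposure, which the design names, stays among the open explanations, and the genes were picked and followed on the same arrays with 1 rat per condition.

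Of the other regroupings, 35 of 35 gave at least the 0 genes of 3000 ppm CO against 5% O2, which a real count of 0 makes certain and which decides nothing about chance. The highest other, 352, followed the slides, which points to a structure of the arrays. For 1000 ppm CO against 5% O2 chance cannot be excluded, with 2 of 35 splits at or above 147 genes; the higher one gave 573 with 1000 ppm CO at 6 h beside the 5% O2 arrays, which also points to a structure of the arrays. For 3000 ppm CO against the mean of the others, 97 drawn splits could be fitted, with the real one at 395 genes and the highest other at 337. These splits do not keep slides together, while the real one mostly does, so they cannot exclude chance. With slide as a random block 0 genes passed and with scan session as a fixed factor 1, so slide is not excluded either. At 2 h and 6 h against 0 h the 10 splits are too few for such a share, with 5 real genes against 1 in the highest other at 2 h and 6 against 7 at 6 h, where 2 splits gave as many.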

How the results depend on the processing

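The settings with scan session, with tissue makeup as covariates and without 1000 ppm CO at 6 h and 5% O2 at 0 h were chosen only after the results were seen. No paired analysis was possible because each array came from a different rat and the labels pair none. The cause of the changes was not tested, except where fewer arrays, fewer genes or fewer residual degrees of freedom come with the setting itself. Signal over background limits what can be read: 72.8% of the genes of 3000 ppm CO against 1000 ppm CO lay under the median level.

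In the order 3000 ppm CO against 1000 ppm CO, 3000 ppm CO against 5% O2, 1000 ppm CO against 5% O2, 3000 ppm CO against the mean of 1000 ppm CO and 5% O2, 3000 ppm CO against air, 1000 ppm CO against air, 5% O2 against air, 2 h against 0 h after exposure, 6 h against 0 h after exposure and 12 h against 0 h after exposure, the counts were 1435, 0, 147, 395, 2, 41, 1, 5, 6 and 4. In the same order, normexp background gave 21, 0, 0, 0, 0, 0, 0, 0, 0 and 0, and shifted the median of all genes by −0.137 in the fourth, 0.229 in the sixth and 0.201 in the ninth contrast. Quantile normalization gave 1302, 0, 41, 227, 2, 16, 1, 5, 6 and 3. The deposited series values gave 1186, 0, 71, 201, 2, 24, 1, 8 (1 higher, 7 lower), 6 and 4, and shifted the median by −0.121 in the first and −0.104 in the fourth. Probes above background on all 12 arrays gave 1136, 1, 141, 353, 0, 24, 0, 4, 5 and 3. No filter on dim probes gave 1200, 0, 57, 100, 54, 123, 73, 4, 5 and 5. The mean over probes gave 1319, 0, 142, 355, 2, 40, 1, 5, 6 and 4. The prior with trend and robust fitting gave 1324, 0, 104, 208, 0, 8, 0, 5, 5 and 4. Slide as a random block (correlation 0.81) gave 0, 0, 0, 0, 3, 0, 0, 7, 7 and 2. Position on the slide gave 1906, 108, 80, 1343, 0, 234, 12, 1, 0 and 1. Scan session gave 1, 0, 153, 1, 0, 0, 0, 1, 2 and 2. Tissue makeup as covariates gave 3695, 1, 0, 776, 0, 0, 0, 0, 0 and 0. Without 1000 ppm CO at 6 h and 5% O2 at 0 h the counts were 672, 2, 5, 0, 0, 2, 0, 0, 0 and 0.

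Slide as a fixed factor could not be fitted for contrasts with 1000 ppm CO; it gave 0 for 3000 ppm CO against 5% O2, 3000 ppm CO against air and 5% O2 against air, and 1, 2 and 2 for the times. In the order 3000 ppm CO against 1000 ppm CO, 3000 ppm CO against 5% O2, 1000 ppm CO against 5% O2, 3000 ppm CO against the mean of 1000 ppm CO and 5% O2, 3000 ppm CO against air, 1000 ppm CO against air and 5% O2 against air, exposure without time gave 1980, 1, 524, 755, 9, 574 and 9. Only 0, 2 and 6 h gave 2298, 108, 153, 1618, 0, 234 and 1. Without the air array the times gave 5, 6 and 4. Leaving out 1 array in turn gave 200 to 2298, 0 to 108, 0 to 1783, 0 to 1618, 0 to 3, 0 to 234, 0 to 1, 0 to 6, 0 to 8 and 0 to 8.

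For each exposed array against the air array, the median count of 2241 genes was 685 with normexp background, 2163 with quantile normalization, 2261 with the series values, 1419 with probes above background on all 12 arrays, 2191 with the mean over probes, 6425 at 1.5-fold, 674 at 3-fold and 808 against the median of the 12 arrays. Of the counts of single arrays, 36 stayed within 1.5 times and 52 did not. For gene lists, 47 camera calls became 3 with the estimated correlation.

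Named genes kept their direction in all settings but normexp background, which turned 22 values. For 3000 ppm CO against 1000 ppm CO these were Or4c103b −0.11, Muc20 −0.20, Hnf4g −0.08, Pabpc2 −0.36, Adrb3 −0.16, Ccnjl −0.05, Vom2r45 −0.39, Vom2r79 −0.02 and Or9k2b −0.27. For 1000 ppm CO against 5% O2 they were Muc20 0.37, Pdia6l1 0.15, Or4c103b 0.51, Olr385 0.51, Nutm2f 0.59, Or6d14 0.49, Or4k42b 0.57 and Gpr31 0.08. For 3000 ppm CO against the mean of 1000 ppm CO and 5% O2 they were Vom2r45 −0.06, Pdx1 −0.08, Pabpc2 −0.04 and Prss46 −0.05, and for 1000 ppm CO against air Or5b104b 0.27. In the other settings 541 values passed as before and 441 no longer did, and leaving out 1 array kept 321 and lost 569.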

Other observations

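The lists in this part were chosen only after the results were seen, and no cause was tested here.

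Genes of cell division, as a list, lay mostly above air in 3000 ppm CO on slide 1 and mostly below it in 5% O2, a difference between exposures that was not tested for the list. Of 21 measured mitotic genes, 18, 20 and 19 were above air in 3000 ppm CO at 0, 2 and 6 h, with medians of 0.21, 0.51 and 0.39, and 8 in 3000 ppm CO at 12 h (median −0.10). In 5% O2 at 0, 2 and 6 h, 18, 17 and 19 were below air, with medians of −0.69, −0.22 and −0.39. Cdk1, the kinase that drives entry into mitosis, was at 0.35, 0.66, 0.44 and −0.23 at 0, 2, 6 and 12 h after 3000 ppm CO and at −1.32, −0.43 and −0.67 at 0, 2 and 6 h after 5% O2. Aurkb went against this, at −2.28 and −0.90 in 3000 ppm CO at 2 and 6 h. In the 4 arrays of 1000 ppm CO the list's medians lay between −0.20 and 0.03.

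Peptide genes of the hypothalamus, a brain region below the striatum, were below air in 1000 ppm CO at 0 and 2 h (medians −1.26 and −1.13) and in 3000 ppm CO at 2 and 6 h (−1.26 and −1.42). They were above it in 1000 ppm CO at 6 h (0.97), where 7 of 8 were higher, and in 5% O2 at 0 h (0.39). The other medians were 0.15 and −0.35 in 3000 ppm CO at 0 and 12 h, 0.11 in 1000 ppm CO at 12 h, and −0.25 and −0.22 in 5% O2 at 2 and 6 h. Oxt, the oxytocin gene, was at −4.48 in 3000 ppm CO at 2 and 6 h and at 1.79 in 1000 ppm CO at 6 h, and Gal, the galanin gene, at 1.27 in the last of these.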
